A study of Danio rerio with 2 samples.

How the data were processed

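Single cells from the midbrain of zebrafish embryos at 2 days post fertilisation were profiled with the 10x Genomics Chromium 3' chemistry, version 3, per the labels' protocols. There were 2 samples in 2 groups, 1 library per group: embryos labelled as siblings and embryos labelled as homozygous for an ENU allele of aars1. How many embryos were pooled in each library is not given in the sources used here. The deposited files hold raw counts, as UMIs per gene and cell barcode, made with Cell Ranger 5.0.0 per the file headers. The submitters' processing notes also name the genome build GRCz11 and Seurat 3, without their roles. The annotation release and the settings for calling cells are not given in the sources used here. The lowest barcodes held 775 and 712 UMIs, so the matrices hold no barcodes of lower depth. Gene symbols were those the deposited files pair with the gene identifiers, and 1190 of the 25113 genes share a symbol with another gene. These were kept apart by identifier in the calculations, though most are printed here by symbol alone. A RefSeq table of the assembly GRCz12tu, another build than that of the files, served only for which genes neighbour aars1 and for gene lengths.

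Cells with at least 300 detected genes and at most 10% of UMIs from mitochondrially encoded genes were kept. The mitochondrial limit took out 928 sibling and 581 mutant barcodes and the gene minimum 0 and 1. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 3091 sibling barcodes (17.2%, where 14.4% was the expected rate). In the mutant library it marked 0.0196%, below the limit of 0.5% fixed for a failed call, and the 1873 highest scores, the expected 12.2%, were removed instead, so doublets were not treated alike in the libraries. Kept were 14064 sibling cells with 49270891 UMIs and 12864 mutant cells with 51312298 UMIs, with medians of 1117 and 1341.5 genes and of 2.62% and 2.39% mitochondrial UMIs.

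Clusters were made from both libraries together without correction between them: log counts per 10000, 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 0). The genes of 11 response lists were left out so that clusters were not built on the responses compared. This gave 37 clusters, 30 of them with at least 50 cells in each library. Clusters were named from 24 cell type marker lists. A cluster took the class with most markers among its 10 leading genes by fold over other cells, with 20 CPM added to both, and needed at least 3 markers that were 1.5-fold higher at 10 CPM or more in each library. It stayed unnamed where another class had at least 3 times as many such markers. The marker lists were fixed before the data were examined, as were the other gene lists, the filters, the rule for named genes and 19 processing alternatives. The naming thresholds were set after seeing the data, as were 4 added alternatives. Neuron-like joins the classes of postmitotic, glutamatergic, inhibitory and monoaminergic or cholinergic neurons. The leading genes of the radial glia-like cluster 10 include the immediate early gene fosab.

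A gene's level in a set of cells is its UMIs summed over the cells and scaled to a fixed total of UMIs, as CPM, and its log2 ratio is that of the mutant over the sibling library with 0.5 counts added to each sum. Levels carry exact Poisson intervals, ratios exact conditional ones and shares of cells Clopper-Pearson ones, all at 95% and all covering counting error only. A count of 0 is given with the share that 3 counts, or the exact bound, would allow. No test across libraries was possible with 1 library per group. A list's value is the median log2 ratio of its members of at least 5 CPM, placed as a percentile among 10000 random lists of the same size matched on expression, which describes these 2 libraries. The 21 pathway lists include 4 main lists (cytosolic tRNA synthetases, ATF4, Nrf2 and p53), and there were 3 brain region lists (forebrain, midbrain and hindbrain). A size rule of 1.5-fold served to count members. With the makeup held equal, levels per cluster were averaged with the mean of both libraries' shares as weights. To compare counts per cell and shares of cells with a UMI, each cell was thinned to 1000 UMIs, which left out 1486 sibling and 1766 mutant cells.

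Genes were named by rule. In all cells these were the 15 highest and 15 lowest log2 ratios among the 4811 genes of at least 20 CPM whose ratio with the makeup held equal had the same sign and a size of at least 0.5. In the neuron-like and precursor-like classes they were the 5 highest and 5 lowest among genes of at least 50 CPM. Each pathway list gave up to 4 members of at least 20 CPM, and a fixed set of stress and cell type genes was always followed. Clone names without a symbol of their own were passed over, 18 among the highest and 1 among the lowest in all cells, and 1 in precursor-like cells. Some genes that the rule takes are not reported here.

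The alternatives were other gene minimums (none, 800) and mitochondrial limits (none, 5%), doublets kept, TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors in R 4.3.3, totals without mitochondrial, ribosomal and haemoglobin genes, the mean over cells, thinned cells, the makeup held equal, other limits on list members, resolutions 0.5 and 2, and genes centred within each library. Those added were leaving out the low-UMI clusters 1 and 12, leaving 194 genes that differed between the libraries out of the clustering, cluster 6 alone for the cycling class, and the synthetase list without aars1. TMM factors were 0.940 and 1.06 and DESeq2 size factors 0.914 and 1.09. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

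The calculations were tested on simulated data, counts for 9277 genes drawn from both libraries' means, 200 of them changed. Genes raised 1.5-fold, 2-fold and 4-fold came out at median log2 ratios of 0.57, 0.99 and 2.00. The intervals held the true value for 88.2% to 97.0% of changed genes, by fold, and for 95.5% of unchanged ones. Of unchanged lists 94% lay between percentiles 2.5 and 97.5, and 100% of lists raised 1.3-fold lay above. The simulated lists were drawn at random, and unchanged genes differed by counting error alone. The 100% is therefore no measure of how often such a rise would be found in the real libraries. With only the cell makeup across clusters changed, 0.166% of 4830 genes passed a log2 ratio of 0.5, and 0% with the makeup held equal. The 0% follows from the setup, in which both libraries shared 1 profile per cluster. Differences of makeup within clusters were not simulated.

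Several limits come from the processing. RNA free in the cell suspension adds UMIs to every droplet: globin genes stood at 352 and 567 CPM in neuron-like cells of the sibling and mutant library, against 703287 and 729044 CPM in erythroid-like cells. A 3' count does not read the coding change of an allele. Whether the libraries were dissected, dissociated or sequenced on the same day is not given in the sources used here, so any such difference is joined to the genotype.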

Results

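Droplet-based single-cell RNA sequencing, which counts mRNA molecules by unique molecular identifiers (UMIs) read near the 3' end, was applied to the midbrain of zebrafish embryos at 2 days post fertilisation. There were 2 libraries, 1 from embryos labelled as siblings and 1 from embryos labelled as mutants for an ENU allele of aars1. The gene aars1 encodes the cytosolic alanyl-tRNA synthetase, which loads tRNA with alanine, and ENU is a chemical mutagen that mostly changes single bases. The study's title names Nrf2, a transcription factor that switches on antioxidant genes. The comparison asks how expression and cell makeup of the midbrain differ in embryos labelled as mutant for this synthetase. The sibling library held 17997 barcodes and 59176315 UMIs, with a median of 1964 UMIs per barcode, and the mutant library 15303 barcodes and 59256226 UMIs, with a median of 2844. After filtering and removal of predicted doublets, 14064 sibling and 12864 mutant cells were kept, with medians of 2727.5 and 3568.5 UMIs. With 1 library per group there was no replicate spread to set a difference against, no test was made across cells, and every interval given is a 95% interval that covers counting error only. Levels are given as CPM, the UMIs of a gene summed over cells and scaled to a fixed total. The median log2 ratio of mutant over sibling across the 9272 genes of at least 5 CPM was 0.12, against −0.06 with TMM factors and −0.08 with DESeq2 size factors, so list medians are also given relative to it.

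The gene the mutant line is named for, aars1 (ENSDARG00000069142), was at 51.4 CPM (49.4 to 53.5) in the sibling library and at 33.0 CPM (31.4 to 34.6) in the mutant library, a log2 ratio of −0.64 (−0.73 to −0.55). It was lower in the mutant library in 28 of the 30 clusters with at least 50 cells in each library. The log2 ratio was −0.69 in neuron-like cells, −0.56 in neuronal precursor-like cells, −0.36 in cycling progenitor-like cells and −0.96 in radial glia-like cells. In erythroid-like cells, where its level was 105 CPM in the sibling library, it was 32.9 CPM in the mutant library (log2 ratio −1.65). This ratio rests on 83 UMIs in 51 sibling cells and 24 UMIs in 66 mutant cells. The erythroid-like cells also differed in median depth (16960 and 7587.5 UMIs) and in G2 and M phase genes (median log2 ratio −2.42). Whether they were in the same state in both libraries was not tested. A base change need not alter a count taken at the 3' end, so the level of aars1 is no check of the genotype label.

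Clusters were named from marker genes, and 13 clusters that shared markers of neurons held 59.7% of sibling cells (58.9 to 60.5) and 53.4% of mutant cells (52.5 to 54.3). Committed neuronal precursor-like cells made up 10.3% (9.80 to 10.8) and 9.71% (9.20 to 10.2), and radial glia and neural progenitor-like cells 3.22% and 3.36%. Cycling progenitor-like cells made up 4.6% of sibling cells (4.26 to 4.96) and 9.68% of mutant cells (9.17 to 10.2). Cluster 6 contributed 514 sibling and 627 mutant cells to this class. Cluster 12, whose cells held few UMIs (medians 2324 and 1317) and whose leading genes were pde6gb, a photoreceptor gene, and histone clones beside dut and an rrm2 gene (ENSDARG00000078069), contributed 133 and 618. With the genes that differed between the libraries left out of the clustering, an alternative chosen after seeing the data, the cycling share was 4.94% and 9.75%. The gap of 5.08 points in this class shrank to 1.23 and 1.27 points at the lower and the higher clustering resolution, to 1.06 with genes centred within each library and to 1.79 among cells with at least 800 genes. Among those deeper cells the neuron-like share turned to 50.5% in the sibling and 53% in the mutant library. The median depth of neuron-like cells was 1949 UMIs in the sibling and 3810.5 in the mutant library. Smaller classes were retinal neuron and photoreceptor-like cells (2.46% and 1.74%), roof plate or floor plate-like cells (0.782% and 1.1%), retinal progenitor-like cells (0.590% and 0.342%), oligodendrocyte precursor-like cells (0.476% and 0.381%), erythroid-like cells (0.363% and 0.513%) and microglia or macrophage-like cells (0.156% and 0.365%). The 8 clusters left unnamed held 16.5% and 17.1%. The largest of them, cluster 1, held 1284 sibling and 1391 mutant cells (9.13% and 10.8%) of few UMIs (medians 928 and 877). Its 10 leading genes were all lens crystallins, and 16 lens markers passed the naming limits in the sibling and 0 in the mutant library.

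**Figure D1:**
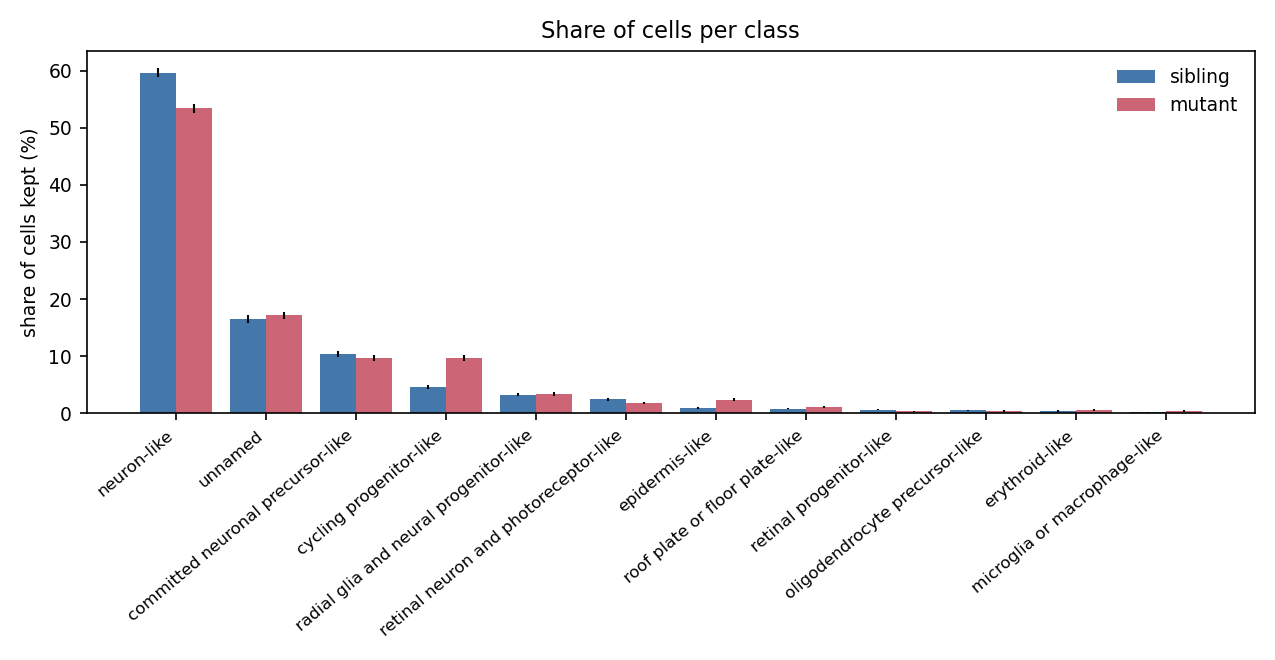
Share of kept cells per class in percent, in the sibling (blue) and mutant (red) library, with exact 95% binomial intervals as vertical lines. Neuron-like cells were at 59.7% and 53.4%, and cycling progenitor-like cells at 4.6% and 9.68%, a gap that shrank to 1.06 points with genes centred within each library. The unnamed share was then 18.6% and 23.5%.

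The other cytosolic tRNA synthetases, which charge tRNAs with the remaining amino acids, were mostly higher in the mutant library. Of the 24 measured members of this list, which includes aars1 and partner proteins of the multisynthetase complex, 23 had a log2 ratio above 0 and aars1 was the exception. The asparaginyl synthetase nars1 went from 71.5 to 124 CPM (log2 ratio 0.79), the threonyl synthetase tars1 from 66.5 to 111 CPM (0.73) and the isoleucyl synthetase iars1 from 22.1 to 33.9 CPM (0.62). The smallest ratios above 0 were those of the scaffold genes aimp2 (0.02) and aimp1a (0.03), which lay below the median of all genes. The list's median was 0.48 (0.43 to 0.53), or 0.36 relative to all genes, and exceeded all 10000 random lists matched on expression (percentile 100). It stayed above 0 with TMM factors (0.30) and DESeq2 size factors (0.28). The 4 measured mitochondrial synthetases had a median of 0.31 at percentile 56.2.

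**Figure D2:**
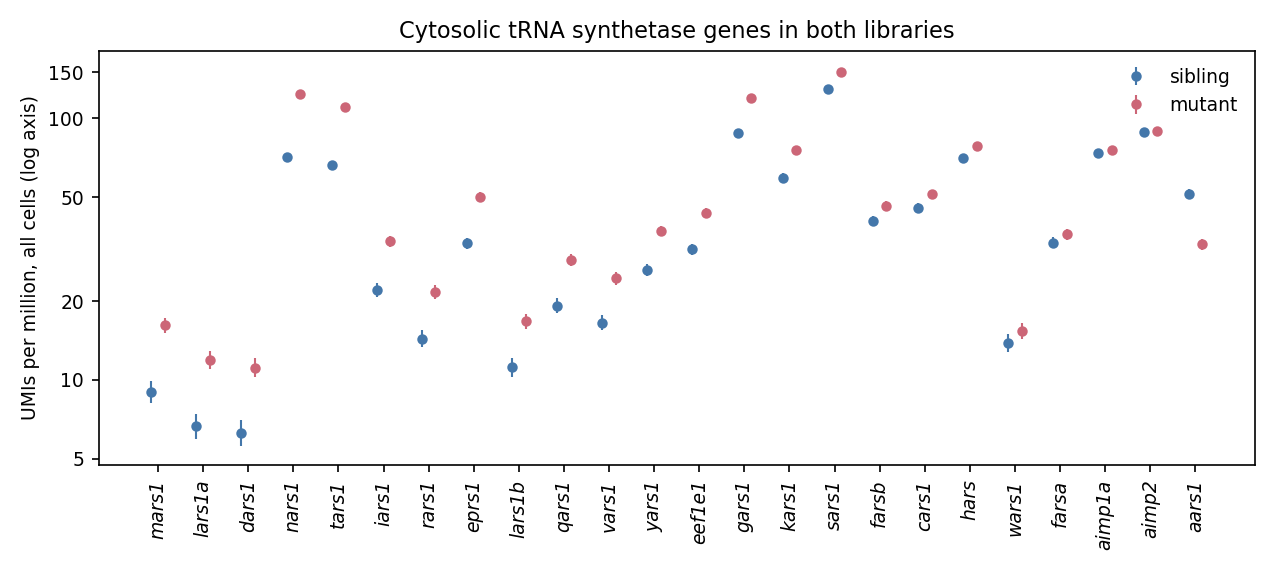
CPM (log axis) of the 24 measured cytosolic tRNA synthetase and partner genes in all cells of the sibling (blue) and mutant (red) library, ordered by their log2 ratio, with exact 95% Poisson intervals. The mutant point lies above the sibling point for 23 genes and below it for aars1 (51.4 and 33.0 CPM).

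Genes of the ATF4 amino acid response, which cells switch on when amino acids run short or uncharged tRNA builds up, were higher in the mutant library. The serine synthesis enzymes phgdh and psat1 went from 37.5 to 101 CPM (log2 ratio 1.42) and from 54.0 to 100.2 CPM (0.89). The cystathionine synthase gene cbsb went from 15.9 to 35.6 CPM (1.17) and the cationic amino acid transporter slc7a3a from 28.6 to 49.6 CPM (0.80). Asparagine synthetase, asns, a standard ATF4 target, was rare at 0.812 and 3.76 CPM (log2 ratio 2.2, 1.71 to 2.74). The stress transcription factors atf3 and ddit3 both had a log2 ratio of 0.62 and the glutathione-degrading chac1 one of 0.27. The ATF4 genes themselves were near level, with 0.05 for atf4a, which turned to −0.13 with TMM and −0.15 with DESeq2 factors, and −0.04 for atf4b, and the ATF4 target trib3 was at −0.04. Of 33 measured members 11 were at least 1.5-fold higher and 0 were as much lower, where random matched lists held 2.03 higher members on average. The list's median was 0.40 (0.34 to 0.42), or 0.27 relative to all genes, at percentile 100. It was 0.22 with TMM and 0.20 with DESeq2 factors.

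By cell class, the ATF4 list stood furthest apart in cycling progenitor-like cells, with a median log2 ratio of 1.21 (1.1 to 1.31), or 1.14 relative to all genes in those cells, and 29 of 39 measured members were at least 1.5-fold higher. In these cells phgdh went from 111 to 340.3 CPM (log2 ratio 1.61), psat1 from 147 to 348 CPM (1.24), cbsb from 27.4 to 111 CPM (2.01) and slc7a3a from 59.3 to 159.7 CPM (1.43). The list's relative median was 0.30 in radial glia-like cells (percentile 100), 0.13 in neuron-like cells (99.2) and 0.10 in precursor-like cells (91.9). Outside the 4 main classes it was 0.38 in retinal neuron-like, 0.27 in epidermis-like, 0.01 in roof or floor plate-like and −0.01 in erythroid-like cells. The cytosolic synthetases had relative medians of 0.88 in cycling progenitor-like, 0.34 in radial glia-like, 0.11 in neuron-like and 0.13 in precursor-like cells, and in cycling progenitor-like cells nars1 went from 54.9 to 252 CPM (2.2) and tars1 from 84.5 to 243 CPM (1.52). Whether the classes differ was not tested. Cluster 6 alone gave a relative ATF4 median of 1.16 and cluster 12 one of 0.62.

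Because cell depth differed, the cells with at least 1000 UMIs (12578 sibling and 11098 mutant cells) were also thinned to 1000 UMIs each. In cycling progenitor-like cells the ATF4 list then gave a mean of 1.60 UMIs per cell in the sibling and 3.01 in the mutant library (13.6 and 19.0 before thinning). In neuron-like cells it gave 1.74 and 1.95 (4.90 and 6.91 before thinning), and in erythroid-like cells 0.956 and 0.978. A UMI of phgdh, which was added to this check after its values were seen, was found in 9.22% (7.09 to 11.7) of thinned sibling and 25.8% (23.2 to 28.5) of thinned mutant cycling cells, against 47.6% and 55.4% before thinning. In thinned erythroid-like cells phgdh was found in 0 of 45 sibling cells, where a share of up to 7.87% is allowed, and in 2.17% of mutant cells. Globin genes filled most of the UMIs of these cells (703287 and 729044 CPM). Low counts in them after thinning are therefore no measure of free RNA in other classes. The median depth before thinning was 7879 and 3384 UMIs in cycling progenitor-like cells and 16960 and 7587.5 in erythroid-like cells.

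The Nrf2 antioxidant list, the response named in the study's title, lay below the median of all genes in the mutant library, and 11 of its 27 measured members had a log2 ratio above 0. The glutathione transferase gstp1 went from 36.1 to 61.1 CPM (log2 ratio 0.76, or 0.43 with the cell makeup held equal) and the thioredoxin reductase txnrd3 from 22.5 to 30.1 CPM (0.42). The glutamate-cysteine ligase subunits gclc and gclm were at 0.23 and −0.03, thioredoxin txn at −0.13, peroxiredoxin prdx1 at −0.10 and esd at −0.13. Nrf2 itself, nfe2l2a, was at 7.83 and 7.70 CPM (−0.03, and between −0.23 and 0.70 over the alternatives), and its inhibitors keap1a, with 22 and 29 UMIs, and keap1b were at 0.33 (between 0.09 and 1.28 over the alternatives) and −0.12. Haem oxygenase hmox1a was lower in the mutant library, at 5.46 and 1.52 CPM (log2 ratio −1.84, and between −2.48 and −1.11 over the alternatives), but the share of cells with a UMI of it was not, at 0.127% of thinned sibling and 0.171% of thinned mutant cells (0.313% and 0.381% before thinning, at median depths of 2727.5 and 3568.5 UMIs). It was found in 0 of 45 sibling and 0 of 46 mutant erythroid-like cells after thinning, which allows up to 7.87% and 7.71% (median depths 16960 and 7587.5 UMIs). As globin fills most of their UMIs, these counts are no measure of free RNA elsewhere. The list's median was −0.03 (−0.06 to 0.03), or −0.15 relative to all genes, at percentile 0.03 of random matched lists. Relative medians were −0.11, −0.13, −0.16 and −0.07 in neuron-like, precursor-like, cycling progenitor-like and radial glia-like cells. The median in all cells turned to 0.13 with cells thinned to 1000 UMIs and to 0.12 as the mean over cells, each near the median of all genes under that setting. In cycling progenitor-like cells, the only class in which these alternatives were run, the relative median lay between −0.25 and −0.05 over the alternatives.

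**Figure D3:**
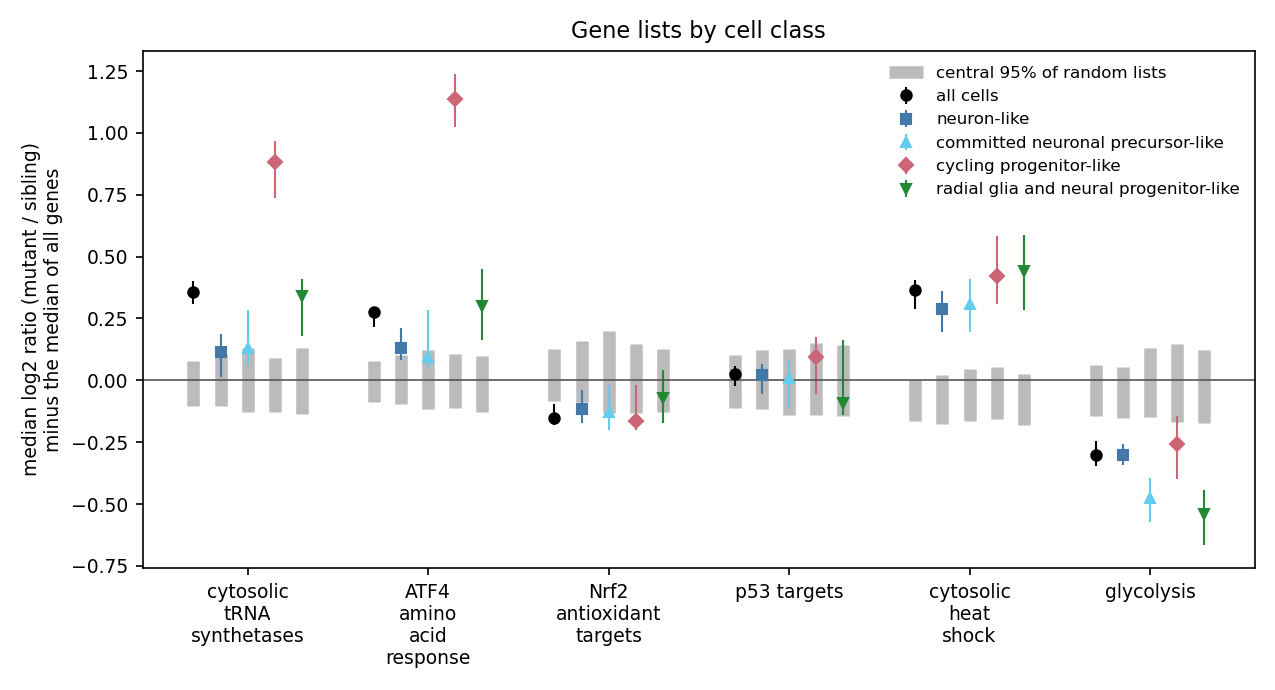
Median log2 ratio of 6 gene lists minus the median of all genes, in all cells and in 4 classes, with counting intervals as vertical lines and the central 95% of random matched lists as grey bars. The ATF4 list reached 1.14 and the synthetases 0.88 in cycling progenitor-like cells, while the Nrf2 list lay between −0.16 and −0.07 in the classes and at −0.15 in all cells, where it came near 0 with cells thinned to 1000 UMIs.

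The p53 target list, which covers arrest and apoptosis genes, had a median log2 ratio of 0.15 (0.10 to 0.18), or 0.03 relative to all genes, at percentile 76.6. It turned to −0.03 with TMM and −0.05 with DESeq2 factors. Among its members foxo3b was at 0.38, mdm4 at 0.29, ppm1da at 0.15 and rrm2b at −0.18. The p53 inhibitor mdm2 was at 0.20, the arrest gene cdkn1a at 0.04 and ccng1 at −0.09, with ranges over the alternatives of −0.004 to 0.57, −0.16 to 0.51 and −0.29 to 0.14. The death genes bbc3 and casp8 were rare, at 0.35 and 0.60 (0.40 to 1.24 over the alternatives). The only member of at least 5 CPM past 1.5-fold was perp (0.68), named after its value was seen. The apoptosis list had a median of 0.04 at percentile 3.97, or −0.09 relative to all genes (−0.11 to 0.12 over the alternatives, so that its side turned), with birc2 at 0.31, casp3a at 0.29, mcl1b at 0.26 and mcl1a at −0.18.

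Cytosolic heat shock genes, the chaperones of misfolded proteins, were higher in the mutant library in each of the 4 main classes. The median over 24 members was 0.49 (0.41 to 0.53), or 0.36 relative to all genes (percentile 100), and 9 members were at least 1.5-fold higher. The levels were 385 and 897 CPM for hsp70l (log2 ratio 1.22), 208 and 469 CPM for dnajb1b (1.17) and 139 and 293 CPM for hsp70.1 (1.08). The list also takes serpinh1b, whose product is a collagen chaperone and not cytosolic, at 6.49 and 33.7 CPM (2.37). The hsp70 copies are near-identical, so how their counts were divided among them is uncertain. Relative medians were 0.29 in neuron-like, 0.31 in precursor-like, 0.42 in cycling progenitor-like and 0.44 in radial glia-like cells. Immediate early genes, often switched on by tissue handling, had a median of 0.14 (percentile 81.6), with fosl1a at 0.65, jun at 0.42 and socs3b at 0.37, and turned to −0.04 with TMM and −0.06 with DESeq2 factors. The unfolded protein response of the endoplasmic reticulum had a median of 0.15 (percentile 90.2), with hspa5 at 0.25, pdia4 and xbp1 at 0.29, hsp90b1 at 0.27 and p4hb at 0.26. That list turned to −0.03 and −0.05 with the same factors.

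Glycolysis genes were lower in the mutant library. The median over 19 members was −0.18 (−0.22 to −0.12), or −0.30 relative to all genes, below all random matched lists (percentile 0), and 3 members had a ratio above 0. The phosphoglycerate mutase pgam1a went from 67.2 to 42.5 CPM (log2 ratio −0.66), the lactate dehydrogenase ldha was at −0.38, the enolase eno1a at −0.32 and the glucose phosphate isomerase gpia at −0.31. Relative medians were −0.30 in neuron-like, −0.48 in precursor-like, −0.26 in cycling progenitor-like and −0.54 in radial glia-like cells.

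Of the remaining lists, ribosomal proteins had a median log2 ratio of −0.10 (percentile 0.02), with rps14 at −0.17 and rpl26 at 0.48. That list was made by name and also takes ribosomal kinases such as rps6kb1b (0.28) and rps6kc1 (0.19). Translation factors were at −0.01 (percentile 12.9), with eef1a1a at 0.36, eif2b4 at 0.32, eif4g2a at 0.29 and eif2b2 at 0.28. Autophagy and lysosome genes were at 0.02 (percentile 1.03), with tfe3a at 0.36, ulk2 at 0.25, laptm4a at −0.20 and ctsd at −0.15. Sterol synthesis was at 0.02 (percentile 5.36), with insig1 at −0.18, srebf2 at −0.06, hmgcrb at 0.04 and fdps at 0.02. The 6 measured interferon and inflammation genes had a median of 0.60 (percentile 99.8). The pair of them above 20 CPM, b2ml and nfkbiab, were at −0.17 and 0.12, while mhc1uba (1.24), cxcl18b (0.68), nfkb2 (0.61) and stat1a (0.60), named after their values were seen, had 10.5 CPM or fewer. S phase genes were at 0.19 (percentile 94.0), with pola1 at 0.57 and rrm2 (ENSDARG00000020711) at 0.49, and G2 and M phase genes at 0.16 (percentile 96.5), with kif4 at 0.71, cdc25b at 0.57 and cenpf at 0.54. Notch genes, which keep neural progenitors undifferentiated, were at 0.13 (percentile 98.9), with notch1b at 0.75, dld and her4.3 at 0.43 and lfng at 0.40. Axon and cytoskeleton genes were at 0.11 (percentile 98.8), with mapta at 1.03, slit1a at 0.91, kif5c at 0.81 and inab at 0.65. Synaptic genes were at 0.07 (percentile 43.7), with pclob at 0.62, syn2a at 0.32, cplx2 at 0.26 and sypb at −0.26. Relative to all genes these last 5 medians were 0.07, 0.04, 0.01, −0.02 and −0.05, and all 5 medians turned below 0 with DESeq2 factors. As the mean over cells the medians of S phase and G2 and M phase genes were 0.42 and 0.59, or 0.29 and 0.46 relative to all genes. Mitochondrially encoded transcripts were at −0.07 (percentile 22.6), with mt-nd4l at 1.64, mt-atp8 at 1.09, mt-nd6 at 0.82 and mt-nd5 at 0.57. Their median turned to 0.03 among cells with at least 800 genes and to 0.04 with at most 5% mitochondrial UMIs.

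Among single genes of at least 20 CPM, 241 met the rule for the highest ratios and 9 that for the lowest, with ratios not set against the median of all genes. The highest included histone genes with near-identical copies, hist1h4l (4 copies, log2 ratios 3.21, 2.4, 2.32 and 1.42), hist2h3c (2.5), H3C13 (2.19) and hist1h2a3 (1.86). They also included the keratins cyt1l (3.35), cyt1 (3.05) and krt4 (2.66), which were at 1.26, 1.22 and 1.35 as the mean over cells, and tcnbb (6.35 to 106 CPM, log2 ratio 4.05, and between 0.90 and 4.57 over the alternatives), leading genes of the epidermis-like cluster 18. With the makeup held equal, cyt1l, cyt1, krt4 and tcnbb were at 2.82, 2.54, 2.15 and 3.47. The fatty acid binding protein gene fabp7b, a leading gene of the roof plate-like cluster 36, went from 11.0 to 39.8 CPM (1.85, and 1.06 with the makeup held equal). The others were serpinh1b, at 1.58 with the makeup held equal, phgdh and mt-nd4l. The lowest were the neuropeptide genes galn (42.7 to 11.6 CPM, log2 ratio −1.88, and −1.27 as the mean over cells), sst1.1 (29.5 to 14.8 CPM, −0.99) and pyya (47.5 to 28.3 CPM, −0.74, and between −1.66 and −0.42 over the alternatives), then pgam1a, aars1, calb2a (−0.44), tspan18a (−0.32) and icn (−0.17), the last 3 of which passed by their ratio with the makeup held equal. Of these, galn and pyya lead the neuron-like cluster 0, calb2a leads cluster 16 and icn cluster 18. The sign of icn turned to 0.54 as the mean over cells and that of tspan18a to 0.12 with at most 5% mitochondrial UMIs.

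Within neuron-like cells the 5 highest genes of at least 50 CPM were hsp70l (395 to 942 CPM, log2 ratio 1.25), dnajb1b (1.22), a hist1h4l copy (1.2), mapta, which encodes the microtubule protein tau (38.9 to 83.1 CPM, 1.1), and hsp70.1 (1.08). The 5 lowest were pgam1a (67.4 to 41.0 CPM, −0.72), pyya (−0.71), the synapse organiser cbln2b (−0.45), the radial glia gene fabp7a (−0.44) and the transcription factor nfia (−0.44), of which pyya and cbln2b are leading genes of cluster 0. In precursor-like cells hist1h4l (1.33), hsp70l (1.28), dnajb1b (1.25), hes2.2 (36.1 to 76.5 CPM, 1.08) and hsp70.2 (1.05) were highest. The chemokine cxcl12a (74.5 to 48.0 CPM, −0.63), ppp1r14bb (−0.58), eno1a (−0.55) and the axon guidance receptor plxna4 (−0.54) were among the lowest. Of the cell type genes followed throughout, the neuronal RNA-binding gene elavl3 was at −0.12 in all cells, gfap at 0.22, her4.1 at −0.02, the glutamatergic gene slc17a6b at 0.22 and the GABAergic gene gad1b at 0.11. The sign of her4.1 turned with cells thinned to 1000 UMIs (0.07).

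Markers of other tissues and brain regions also moved with the group. Lens markers were almost confined to the sibling library, at 202 CPM summed over 24 genes against 4.37 CPM (log2 ratio of the sums −5.53), and with clusters 1 and 18 left out they were at 48.8 and 4.23 CPM. Epidermis markers summed to 241 and 635 CPM (1.40), but without the epidermis-like cluster 18, which held 0.896% of sibling and 2.3% of mutant cells, the log2 ratio was −0.18. Markers of the retinal pigment epithelium, most of which are also on the neural crest and pigment list, summed to 28.7 and 65.2 CPM (1.18). Neural crest and pigment markers summed to 215 and 279 CPM (0.38) and mesenchyme and cartilage markers to 1614 and 1699 CPM (0.07), nearer to level than the medians over their members. The medians over members were −7.08 for lens, 1.28 for epidermis, 1.62 for pigment epithelium, 0.94 for neural crest and pigment, and 0.65 for mesenchyme and cartilage. They were −0.70 for microglia or macrophage (3 members), −0.16 for erythroid, −0.05 for retinal progenitor, −0.07 for retinal neuron and photoreceptor, 0.43 for pericyte or smooth muscle, −0.01 for endothelium and 0.08 for cranial ganglion or placode markers. Forebrain markers had a median of 0.32 (percentile 99.9, or 0.20 relative to all genes, 0.12 with the makeup held equal and 0.05 with members of at least 20 CPM), midbrain markers 0.15 (93.1) and the 4 measured hindbrain markers 0.34 (82.9). The medians of markers of neural classes were 0.18 for inhibitory, 0.10 for glutamatergic and 0.10 for monoaminergic or cholinergic neurons, −0.00 for postmitotic neurons, 0.10 for committed precursors, 0.07 for cycling progenitors, 0.09 for radial glia, 0.07 for roof or floor plate and 0.06 for oligodendrocyte precursors. The lists for neutrophils, skeletal muscle and hatching gland, liver or gut had under 3 measured members.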

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

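The pair of differences given here came from a comparison of the 4 main classes over all pathway lists, and which lists stood out was known only after their values were seen, as was the split by cluster. S phase genes lay below the median of all genes in neuron-like cells of the mutant library (relative median log2 ratio −0.17, percentile 0.01 of random matched lists) and at 0.05 in radial glia-like cells (percentile 98.2), a difference of 0.22. In radial glia-like cells the list's median of 0.16 had a counting interval of 0.09 to 0.22 that holds the median of all genes, 0.11, so that class was not apart from it beyond counting error. Mitochondrially encoded transcripts lay below it in neuron-like cells (−0.28, percentile 0.54) and at 0.02 in cycling progenitor-like cells (percentile 97.8), a difference of 0.30. In cycling progenitor-like cells the counting interval of the list's median, 0.074 to 0.138, lay just above the median of all genes, 0.071, but this came from cluster 12 (relative median 0.34, percentile 99.9), and cluster 6 alone was at −0.08 (percentile 76.1), where the counting interval of the median, −0.02 to 0.09, holds the median of all genes, 0.08. Neither difference between classes was tested, since each class has 1 library per group, and no explanation was weighed.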

How the results depend on the processing

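Tests chosen only after the result was seen were those without clusters 1 and 12, without the differing genes in the clustering, on cluster 6 alone and on the synthetases without aars1. No paired analysis was possible because each group has 1 library and no test was made. Of the values compared under the alternatives, those of class shares stayed within their counting interval in 18, moved in 9 and turned direction in 1. For aars1 these counts were 10, 2 and 0, for the 4 main list medians 40, 15 and 2, for other list medians 169, 116 and 20, and for named genes 398, 192 and 10. Relative to all genes the ATF4 median ranged from 0.21 to 0.30, the synthetases from 0.28 to 0.38, Nrf2 from −0.18 to 0.00 and p53 from −0.06 to 0.07. The side of the median of all genes also turned for S phase (−0.03 to 0.29), G2 and M phase (−0.07 to 0.46), apoptosis (−0.11 to 0.12), ER unfolded protein response (−0.12 to 0.09), immediate early genes (−0.03 to 0.13), Notch (−0.06 to 0.08), synaptic vesicle (−0.15 to 0.02), axon (−0.07 to 0.03) and midbrain markers (−0.02 to 0.05). In cycling progenitor-like cells the ATF4 median relative to all genes ranged from 1.01 to 1.16. Where a value turned or moved under a scaling, the alternative subtracts 1 amount from every ratio and that is the cause; elsewhere the cause was not tested. Depth limits genes of few UMIs, such as keap1a (22 and 29) and casp8 (39 and 62).

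With TMM factors the log2 ratio of aars1 was −0.82, and the medians were 0.30 for synthetases, 0.22 for ATF4, −0.21 for Nrf2 and −0.030 for p53. With DESeq2 size factors these were −0.84, 0.28, 0.20, −0.23 and −0.051. Medians with a counting interval above 0 that turned below 0 with TMM and DESeq2 were midbrain markers (−0.028 and −0.049), ER unfolded protein response (−0.029 and −0.051), immediate early genes (−0.035 and −0.057), G2 and M phase (−0.019 and −0.041), Notch (−0.049 and −0.071), synaptic vesicle (−0.11 and −0.13), axon (−0.072 and −0.093) and p53 in cycling progenitor-like cells (−0.013 and −0.035), and S phase with DESeq2 alone (−0.0066). Apoptosis, autophagy and sterol synthesis, whose intervals held 0, also turned below 0 with both. Of single genes atf4a turned to −0.13 and −0.15, and mdm2 to −0.004 with DESeq2. With the total without mitochondrial, ribosomal and haemoglobin genes the Nrf2 median was −0.073. As the mean over cells Nrf2 was 0.12, p53 0.19, synaptic vesicle −0.020, her4.1 0.079, ccng1 0.14 and icn 0.54. With cells thinned to 1000 UMIs Nrf2 was 0.13, her4.1 0.070 and icn 0.27. With doublet calls kept her4.1 was 0.0015. With at most 5% mitochondrial UMIs ATF4 was 0.43, tspan18a 0.12 and mitochondrially encoded transcripts 0.040, which were 0.029 with at least 800 genes per cell. With members of at least 20 CPM the synthetases were 0.40 and p53 0.062. With any member that had a count in both libraries Nrf2 was 0.082 and p53 0.20.

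For class shares, in points of mutant minus sibling, at least 800 genes per cell gave 2.55 for neuron-like, −2.78 for precursor-like, 1.79 for cycling progenitor-like and −0.949 for radial glia-like cells. The neuron-like difference was −3.20 at resolution 2 and −4.40 with cells thinned. The cycling difference was 1.23 at resolution 0.5, 1.27 at resolution 2 and 1.06 with genes centred within each library. For unnamed cells the difference was 5.87, 1.92 and 4.90 under these settings, against 0.64 as reported. The radial glia-like difference was 1.05 with doublet calls kept.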

Other observations

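Tests chosen only after the result was seen were those of aars1 and the histones with the makeup held equal, of the ATF4 list with thinned cells, in cluster 6 and against immediate early genes, and of histone UMIs per cell in cluster 6 and in erythroid-like cells, and the descriptions of single classes, clusters and gene length were likewise chosen after seeing the data. In erythroid-like cells (51 sibling and 66 mutant cells) all 43 measured G2 and M phase genes were lower in the mutant library, with a median log2 ratio of −2.42 (−3.05 to −2.20), and 41 of them were at least 1.5-fold lower. The centromere protein gene cenpf had 64 UMIs in the sibling and 6 in the mutant library. The median depth of these cells was 16960 and 7587.5 UMIs. In retinal neuron-like cells the Notch list had a median of 0.76 (0.59 to 0.85), with 15 of 24 members at least 1.5-fold higher, and glycolysis genes a median of 0.44, above 0 where the 4 main classes lay below. In roof or floor plate-like cells S phase genes had a median of 0.88 (0.55 to 1.23) and G2 and M phase genes one of 0.92 (0.50 to 1.46). In epidermis-like cells immediate early genes were lower in the mutant library (median −0.62) and genes of the ER unfolded protein response higher (0.59).

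Among clusters whose leading genes did not pass 1.5-fold between the libraries, the share of cluster 2, led by barhl1a, tcf7l2 and pou4f2, had a log2 ratio of −0.52 (−0.64 to −0.39). That of cluster 3, whose leading genes include sox14, pax7a and the inhibitory gene gata3, was −0.37, that of cluster 7, led by tfap2b and etv1, −0.31, and that of cluster 14, led by tal1 and gata3, 0.27. Depth differed too, with medians of 1879 sibling and 3020.5 mutant UMIs in cluster 2. Among cells with at least 800 genes the neuron-like share as a whole turned to 50.5% in the sibling and 53% in the mutant library. The shares of single clusters were not checked that way. Cluster 28, led by the forebrain genes eomesa, emx3, tbr1b and foxg1a, held 46 sibling and 106 mutant cells, but 3 of its leading genes passed 1.5-fold. The neuropeptide gene galn went from 79.7 to 17.7 CPM within neuron-like cells. Across 8520 genes with a known length, 91.9% of those measured, the log2 ratio rose with gene length (Spearman 0.25 across genes, which are not independent replicates, and 0.23 with the makeup held equal), from a median of 0.04 among genes under 8979 bases to 0.21 among those over 49846 bases.

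The lower level of aars1 is not that of its wider surroundings: the 20 measured neighbours, 10 on either side, had a median log2 ratio of 0.17 and ranged from −0.57 to 0.57. In the gene order of GRCz12tu the nearest of them lay 2 genes away on 1 side (sf3b3) and 13 on the other (arl2bp). The closest genes were thus mostly not measured. With the makeup held equal the log2 ratio of aars1 was −0.70, so another makeup across the clusters does not account for the lower level. Differences of makeup within clusters were not tested. A lower level of the mutant mRNA itself, through decay or lower transcription, and an effect of the line's variants on mapping were not tested and may each contribute.

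The ATF4 list stood highest in cycling progenitor-like cells, with a relative median of 1.01 when every cell was thinned to 1000 UMIs. Thinning leaves each cell's expected proportions as they were, so this value argues only against the weight of deep cells in the sums. Depth that goes with cell state was not tested. The low-UMI cluster 12 is argued against by a relative median of 1.16 in cluster 6 alone. Stress from handling could raise such genes, and immediate early genes in the same cells had a relative median of 0.033, but handling is joined to the library and the heat shock list was higher in each of the 4 main classes, so this cannot be told apart from the genotype. The aars1 genotype stays among the open explanations, as untested.

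Histone genes were higher in the mutant library, and the sum over 44 of them, with a log2 ratio of 1.06 (835 to 1738 CPM), argues against reads moved among these near-identical copies. Reads gained from outside the 44 genes were not tested. The sum's value of 0.92 with the makeup held equal argues against another makeup across the clusters, while differences within clusters were not tested. For free RNA, histone UMIs per cell were higher by 1.38 in neuron-like and 1.40 in precursor-like cells, but changed by −1.14 (−1.88 to −0.40) in erythroid-like cells, and the CPM by 293 in neuron-like and −36.7 (−91.8 to 18.7) in erythroid-like cells, which counts against it and passes the bound set for excluding it. That bound took erythroid-like cells to make no histone mRNA, but their own G2 and M phase genes were lower in the mutant library (median −2.42), and the 1.39 UMIs per cell they held there (1.12 to 1.71) are not fewer than the neuron-like rise, so free RNA stays open for neuron-like and precursor-like cells, though only if nearly all of those UMIs were free and sibling droplets held almost no free histone RNA. In cluster 6 the rise in histone UMIs per cell, from 35.6 to 77.2, was 30.1 times that in neuron-like cells (1.17 to 2.55), more than free RNA spread evenly could give. Most replication-dependent histone mRNAs lack a poly(A) tail, and the S phase list was near level in cluster 6 (median 0.01), so a change in tailed histone mRNA, in its capture or in cycle stage stays open, as does the genotype.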
